A study of Mus musculus with 8 samples.

How the data were processed

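Per the labels, epididymal adipose tissue of polygenic obese mice was profiled on 8 arrays of 2 channels, 4 at day 5 and 4 at day 14, each setting a pool of 4 or 5 mice fed CLA against a pool fed LA. Per the labels, CLA carried Cy5 on arrays 1 and 2 of each day and Cy3 on arrays 3 and 4. The labels call the pools pools of different mice; whether arrays with the same number, or any 2 arrays, share a pool is not given in the sources used here, and each array was taken as a replicate. The deposited table holds 22393 probes with 1 value per array, none missing and none exactly 0. The scanner settings, background treatment, spot filters and normalization method behind the values are not given in the sources used here, and neither are intensities, so signal over background could not be examined; the number of arrays limits the precision.

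The deposited values were taken as log10 ratios of the 2 channels, a unit inferred from the values and stated nowhere in the sources. The basis was the size of the spots with a strong dye signal (median size 1.89 as deposited, or 6.29 log2 units), the spread of repeated probes, and the usual output of 2-colour arrays of this maker. Repeated probes of the 48 genes with 10 or more probes had a median SD of 0.07 to 0.14 log2 units per array after conversion. Values were multiplied by 3.32 to give log2. If they were log2 already, log2 values and standard errors would be 3.32 times smaller and fold changes smaller too, whereas p-values, signs and calls, apart from the test against a 1.2-fold change, would stand. Column medians as deposited were −0.0033, −0.001, −0.0176 and 0.0026 for day 5 and −0.0049, −0.0022, 0.0109 and 0.0042 for day 14, so the authors had likely centred each array; no further centring was done in the fits given first.

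Neither the table nor the labels state which channel is the numerator. The design written before the data were examined said to decide from the correlation across genes between arrays of opposite dyes whether arrays 3 and 4 were still to be turned. That correlation was negative (median r −0.36 within a day, from −0.61 to 0.03, and −0.40 between days), whereas arrays with the same dyes correlated positively (0.47 and 0.54). By that rule arrays 3 and 4 would have been turned. It was set aside after the values were seen, and the values were used as deposited, with all arrays read as CLA over LA. The reason for not turning them lay in the orientation difference, that is the mean of the 4 arrays of a day with arrays 3 and 4 turned. It exceeded 2 log2 units in size on both days for 473 probes without a single gene symbol and 16 with one. Spots with signal in 1 dye do so on arrays whose sign has been turned. The mean of the 4 arrays as deposited exceeded that size on both days for only 1 probe. Signs on single arrays were not counted. These counts bear only on turning, not on which diet is the numerator. The orientation difference, which turning would have made the effect, correlated between days across genes with r 0.75, against 0.36 for the mean of the 4 arrays. Between the probes of 1030 genes with a pair of probes it correlated with r 0.12 at day 5 and 0.06 at day 14, against 0.23 and 0.31 for the mean. Counts with arrays 3 and 4 turned are given beside those without, and so are the values of several genes and lists. The sign of Ucp1 on the day 14 arrays was also seen before the choice.

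Of the probes, 18218 carried 1 gene symbol, 16 several and 4159 none. Probes with several or no symbols stayed in the probe tests and were left out of the gene tests. For 18175 probes the symbol was matched by Entrez number to a mouse gene table (GRCm38.p6, names only), which changed 0 symbols. A gene's value on an array was the mean of its probes, giving 16504 genes, 1193 of them with more than 1 probe; 567 of those had probes of opposite sign at day 14. All sample columns were used.

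Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 8 arrays, with a mean for each day and 1 dye term, for the comparisons day 5, day 14 and day 14 minus day 5. Probes and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 26 gene lists (698 entries, 632 of them measured) were written from general knowledge ahead of the values. They covered lipid droplet and adipocyte markers, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, fatty acid oxidation, uncoupling and thermogenesis, the respiratory chain, the tricarboxylic acid cycle, glycolysis, insulin and glucose handling, apoptosis, inflammatory cytokines and acute phase, macrophage markers, T and B cell markers, neutrophil and mast cell markers, interferon response, extracellular matrix and fibroblast markers, endothelial markers, mesothelial markers, cell proliferation, epididymis and testis markers, skeletal muscle and blood markers, integrated stress and unfolded protein response, oxidative stress and metallothioneins, heat shock, ribosomal proteins and immediate early genes. They were tested with camera at a preset correlation of 0.01, adjusted over the lists, and also with camera with an estimated correlation and with fry; members were called over all genes and adjusted over the list alone.

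Genes named in the text followed a rule set in advance. It took the 10 largest rises and falls among genes past the threshold with 4 arrays on the same side (5 and 5 for the difference) or, where none passed, the 5 of each sign with the smallest p, given as not passing. It also took up to 4 members per list with the smallest p, and a set of genes at both days, among them Scd1, Lep, Adipoq, Pparg, Fasn, Lpl, Fabp4, Tnf, Ucp1, Ucp2 and Cpt1a, of which Ucp2 was not measured by a probe of its own. Since the fit of all arrays called no gene, the first part of the rule was also applied to the fit of the day 14 arrays alone, a use added after the results were seen. The testis and epididymis genes named were chosen after their values were seen, and so were Pfkfb3 and the members named because a count of 5 or fewer called them. Unnamed transcripts (RIKEN and similar symbols) were counted and not described.

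The alternatives set in advance were centring on the median, centring with scaling, no dye term, the arrays of 1 day alone, the array number as a block, arrays averaged in pairs as dye swaps, robust eBayes, a test against a 1.2-fold change, the mean or 1 probe per gene, and each array left out in turn. Arrays weighted by quality, arrays 3 and 4 turned, a dye term for each day, only probes with 1 gene symbol, day 5 arrays 1 and 3 left out together, gene lists with the arrays of 1 day, and the gene test on the day 14 arrays alone with its repeats were added later. Calls were also counted under other sign patterns of the arrays of a day and other splits of the 8 arrays. The fits were tested on simulated data, with 200 of 22393 probes changed in each of 5 sets (seed 11): at a 2-fold change the fit of all arrays called 70.4% and that of the day alone 57.2%, and at 1.5-fold 40.8% and 22%. Of 762 and 672 probes called there, 12 and 13 had not been changed. The simulated errors were normal and independent between probes, with the estimated spread of each probe taken as its true one. The real fit of all arrays called 0 probes at day 14, so these rates need not hold for the real arrays. Files were read and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Left out were pathway databases, which were not used here, and any comparison of single mice, since each channel was a pool.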

Results

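Gene expression in epididymal adipose tissue of polygenic obese mice was measured on 8 arrays of 2 channels each. Every array set RNA of mice fed conjugated linoleic acid (CLA), a mixture of isomers of linoleic acid, directly against RNA of control mice fed linoleic acid (LA). The keywords of the labels name adiposity, lipid metabolism and apoptosis as the subjects of the study. Each RNA was a pool of 4 or 5 mice, and 4 arrays were made from mice at day 5 and 4 from mice at day 14. On arrays 1 and 2 of each day the CLA pool carried Cy5, and on arrays 3 and 4 it carried Cy3. Whether arrays of a day share pools is not given in the sources used here, so the p-values measure only the spread between these arrays. Each array gave a value for all 22393 probes. The probes with 1 gene symbol covered 16504 genes. The number of arrays, 4 per day, limits the precision.

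The ratios below are given as CLA over LA on a log2 scale, which is the likely direction and not a stated one. Its basis is that CLA was the treatment and that Ucp1 was above 0 on all 4 day 14 arrays as deposited, so the direction, the call and the rank of Ucp1 below rest on a value used for the choice and are no independent finding. Spots with a strong dye signal behaved as they would on arrays whose sign the authors had already turned. This bears only on whether arrays 3 and 4 were still to be turned. It would look the same were every ratio LA over CLA, in which case all signs given here would be reversed. Of probes without a single gene symbol, 473 had an orientation difference over 2 log2 units in size on both days. That difference is the mean of the 4 arrays of a day with arrays 3 and 4 turned. For each of the 473 probes, arrays 1 and 2 averaged below arrays 3 and 4 on both days. Signs on single arrays were not counted. Only 1 probe had a mean of the 4 arrays, as deposited, over that size on both days. A rule set in advance would have turned the sign of arrays 3 and 4, because arrays of opposite dyes correlated negatively across genes (median r −0.36 within a day, where genes are not independent replicates). That rule was not followed, and this choice decides the results. With arrays 3 and 4 turned, limma called 3752 probes at day 5 and 3764 at day 14, and camera called 0 gene lists at either day. The day 14 arrays alone then gave 5248 genes in place of 260, with Ucp1 at −0.08 (adjusted p = 0.59) and Nnat at 0.67 (0.12), and 14 of the 20 genes named first below had the other sign. Among those 14, Sucnr1 (0.69, limma adjusted p = 0.018), Mest (0.53, 0.021), Tmem45b (0.40, 0.032), Hsd11b1 (0.42, 0.042) and Hsd17b12 (−0.30, 0.043) were called the other way. The rest of the 14 were not called. Values were taken as log10 ratios and multiplied by 3.32. If they were log2 already, every log2 value and standard error here is too large by that factor and every fold change is overstated.

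At day 14, Ucp1, which encodes the uncoupling protein of brown and beige adipocytes, had the largest rise in the direction taken here, a choice its own values had entered. Its log2 ratio was 3.51 ± 0.10 (SE, n = 4 arrays), or 11.4-fold, in the fit of the 4 day 14 arrays alone (limma, adjusted p = 0.0025). Olr1, a receptor for oxidised lipoprotein, rose by 1.82 ± 0.11, or 3.53-fold. The largest fall was that of the imprinted gene Nnat (neuronatin), which fell by 4.28 ± 0.27 on the log2 scale, a difference of 19.5-fold. Car3, an abundant carbonic anhydrase of adipocytes, fell by 2.93 ± 0.23, and Adipoq, which encodes the adipocyte hormone adiponectin, fell by 2.03 ± 0.29 (4.09-fold, adjusted p = 0.047). In all, 260 of the 16504 genes were called in that fit, 88 higher and 172 lower. With the dye term removed, each had its 4 arrays on the same side of 0. A call from these same arrays favours that, so it is no separate evidence.

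The planned test was the fit of all 8 arrays, in which limma called 0 genes and 0 probes at day 14. There, 1612 genes (700 higher and 912 lower) and 2054 probes (884 higher and 1170 lower) had an unadjusted p under 0.05, and the smallest adjusted p was 0.179 for genes and 0.223 for probes. The fit of the day 14 arrays alone had been planned as an alternative for probes. Its use for genes was added, and it was brought forward, after the fit of all arrays had called none. It called 96 probes, 27 higher and 69 lower. With all 8 arrays weighted by quality, an alternative added later, limma called 393 probes at day 14, 165 higher and 228 lower. The residual spread (root mean square) ran from 0.235 to 0.56 log2 units on the day 5 arrays and from 0.198 to 0.24 on the day 14 arrays. The fit of all arrays shares 1 estimate between them. Of the 260 genes, 222 had an unadjusted p under 0.05 in the fit of all arrays. That fit takes its day 14 ratios from the same 4 arrays, so this overlap is no separate evidence. Without array 1, without array 2 or without the dye term, the day 14 arrays alone called 1 gene, Ucp1. In the same fit, 68 genes were called without array 3 and 156 without array 4.

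The other genes with the largest called rises fell into several functions. Timp1, an inhibitor of matrix metalloproteinases, rose by 1.60 ± 0.23 (SE, n = 4), and Pla2g2e, a secreted phospholipase, rose by 1.45 ± 0.18. Pdk4, a kinase that restrains pyruvate dehydrogenase, rose by 1.47 ± 0.20, and Fabp3, a fatty acid binding protein of muscle and brown fat, rose by 1.31 ± 0.17. Hsd17b12, an enzyme of fatty acid elongation, rose by 1.36 ± 0.08, and Chac1, a glutathione-degrading enzyme induced by stress, rose by 1.26 ± 0.13. Among the falls, Sfrp5, a secreted inhibitor of Wnt signalling, fell by 2.04 ± 0.17, and Apcdd1, another Wnt inhibitor, fell by 1.79 ± 0.15. Mest, an imprinted gene linked to adipocyte size, fell by 1.83 ± 0.11, Hsd11b1, which regenerates active glucocorticoid, fell by 1.59 ± 0.11, and Sucnr1, the succinate receptor, fell by 1.53 ± 0.13. The log2 ratio of Tmem45b was −2.38 ± 0.10 and that of the glutamate transporter Slc1a3 was −1.68 ± 0.24, both called. Adjusted p-values of these 20 genes in the day 14 fit ranged from 0.0025 to 0.047 for the rises and from 0.0072 to 0.047 for the falls. In the fit of all arrays they were 0.18 to 0.33 and 0.24 to 0.37. Without array 1 or without array 2, Ucp1 alone stayed past the threshold.

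**Figure D1:**
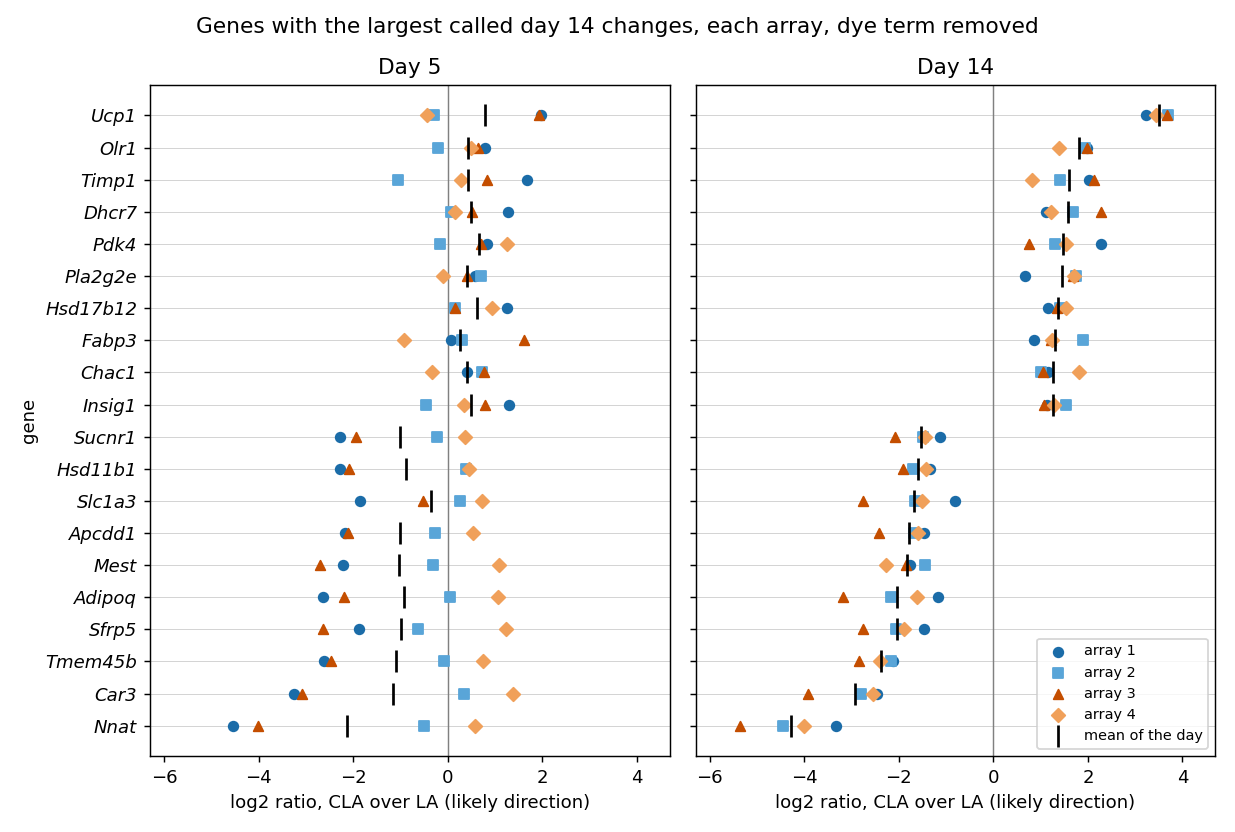
Log2 ratio of CLA over LA (likely direction) on each array at day 5 and day 14, with the dye term removed, for the 10 genes with the largest rises and the 10 with the largest falls called from the day 14 arrays alone; points are arrays and vertical bars are day means. The genes were chosen with their 4 day 14 arrays on the same side of 0, so that agreement, and its contrast with day 5, is no result. At day 5 arrays 2 and 4 often lie apart from arrays 1 and 3, as for Adipoq.

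Macrophage markers rose at day 14: 30 of 33 measured members lay above 0, with a median log2 ratio of 0.60 (camera adjusted p = 6.5e-20, and adjusted p = 0.37 with an estimated correlation). Adgre1, a surface marker of macrophages, stood at 0.84 ± 0.20 (SE, fit of all arrays), the lipid receptor Trem2 at 1.00 ± 0.22, the lysosomal protease Lgmn at 0.74 ± 0.16 and the complement gene C1qc at 0.51 ± 0.13. In limma's fit of all arrays 0 members were called over all genes, 26 had an unadjusted p under 0.05, and 25 rose when adjusted over the list alone. With the day 14 arrays alone 0 were called over all genes and 26 rose adjusted over the list alone. With arrays 3 and 4 turned the median was 0.20 (adjusted p = 0.5). The list median was 0.90, 0.34, 0.80 and 0.14 on the 4 arrays.

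Lipid droplet and adipocyte markers fell, with 23 of 28 members below 0 and a median of −0.48 (camera adjusted p = 2.2e-05, and adjusted p = 0.56 with an estimated correlation). With the day 14 arrays alone, 7 members fell over all genes and 17 when adjusted over the list alone, where 2 members rose. Plin4, a lipid droplet coat protein, was among the 7, with a 2.83-fold difference. With arrays 3 and 4 turned the median of the adipocyte list was 0.34 (adjusted p = 0.98). In the fit of all arrays 0 were called over all genes, 7 lay below 0 at an unadjusted p under 0.05, and only Nnat fell when adjusted over the list alone. Endothelial markers also fell, with 14 of 15 members below 0 and a median of −0.32 (camera adjusted p = 5.1e-05, and adjusted p = 0.56 with an estimated correlation). Cldn5, a tight junction protein of vessels, fell by 0.94 ± 0.13, the adrenomedullin co-receptor Ramp2 by 0.89 ± 0.11 and the receptor Tie1 by 0.79 ± 0.08 with the day 14 arrays alone. These were the 3 members called over all genes there, against 11 adjusted over the list alone. In the fit of all arrays 0 were called in either way and 4 lay below 0 at an unadjusted p under 0.05 (limma), and with arrays 3 and 4 turned the list median was −0.24 (adjusted p = 0.5). All 12 mesothelial markers lay below 0, with a median of −0.41 (camera adjusted p = 5.1e-05, and adjusted p = 0.37 with an estimated correlation). Of them, 2 fell over all genes with the day 14 arrays alone and 6 adjusted over the list alone, against 1 in the fit of all arrays. The mesothelial median was 0.05 (adjusted p = 0.81) with arrays 3 and 4 turned. Among them, the log2 ratio of keratin Krt19, which was called, was −0.62 ± 0.07, and that of Upk1b, which was not, was −1.13 ± 0.19.

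Genes of cholesterol synthesis and uptake rose, with 15 of 19 members above 0 and a median of 0.37 (camera adjusted p = 1.1e-06, and adjusted p = 0.43 with an estimated correlation). Dhcr7, the last enzyme of one branch of cholesterol synthesis, rose by 1.57 ± 0.19, Insig1, a sterol-regulated brake on that pathway, by 1.26 ± 0.10, and Lss, lanosterol synthase, by 1.02 ± 0.09 with the day 14 arrays alone. These 3 were called over all genes, and 12 rose and 1 fell adjusted over the list alone, against 5 that rose in the fit of all arrays. Genes of fatty acid and triglyceride synthesis had a median of 0.13, with 16 of 24 above 0, and were called higher (camera adjusted p = 0.0046, and adjusted p = 0.56 with an estimated correlation). The members did not all move one way. Me1, which supplies NADPH, rose by 1.10 ± 0.12, Acss2, acetyl-CoA synthetase, by 0.93 ± 0.12 and Agpat2, an acyltransferase, by 0.95 ± 0.14. With the day 14 arrays alone 4 of them rose and 2 fell over all genes, and 9 rose and 5 fell adjusted over the list alone, against 4 that rose in the fit of all arrays. Turning arrays 3 and 4 gave medians of −0.10 for cholesterol (adjusted p = 0.5) and −0.05 for fatty acid synthesis (0.81).

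Genes of uncoupling and thermogenesis rose, with 9 of 11 members above 0 and a median of 0.22 (camera adjusted p = 5.1e-05, and adjusted p = 0.14 with an estimated correlation). This was the single list of day 14 that fry also called (adjusted p = 0.01, against 0.052 with the day 14 arrays alone). With those arrays alone fry called 1 list, insulin and glucose handling, lower (adjusted p = 0.033). The thermogenesis list holds Ucp1, whose sign entered the choice of direction. The list was not tested without Ucp1, so its calls are no independent finding. Besides Ucp1, Cox8b rose by 0.87 ± 0.07, Elovl3, an elongase of brown fat, by 0.82 ± 0.11 and Cox7a1 by 0.61 ± 0.07 with the day 14 arrays alone. These 4 were called there over all genes and 5 adjusted over the list alone, against 6 in the fit of all arrays. Genes of fatty acid oxidation had a median of 0.10, with 16 of 23 above 0 (camera adjusted p = 0.00016, and adjusted p = 0.56 with an estimated correlation). Pdk4 was the 1 member called over all genes, against 6 that rose adjusted over the list alone, and 1 did in the fit of all arrays. Extracellular matrix and fibroblast markers had a median of 0.14, with 23 of 38 above 0 (camera adjusted p = 0.00036, and adjusted p = 0.56 with an estimated correlation). Thbs2, a matrix glycoprotein, rose by 0.83 ± 0.07 and periostin, Postn, by 0.78 ± 0.11. In all, 5 members rose over all genes with the day 14 arrays alone, and 16 rose and 5 fell adjusted over the list alone, against 6 that rose in the fit of all arrays. Turning arrays 3 and 4 gave medians of −0.08 for thermogenesis (adjusted p = 0.98), 0.01 for fatty acid oxidation (0.92) and 0.22 for the matrix (0.5).

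In total camera called 15 of the 26 lists at day 14, 10 higher and 5 lower, with 11 not called (adjusted p 0.067 to 0.77). None of the 15 calls held with an estimated correlation (adjusted p 0.14 to 0.58). Inflammatory cytokines and acute phase genes were among those not called (median 0.07, adjusted p = 0.067). So were apoptosis genes (median 0.04, adjusted p = 0.19), genes of insulin and glucose handling (−0.02, 0.51), the respiratory chain (−0.03, 0.12) and the tricarboxylic acid cycle (−0.02, 0.77; its camera direction was upward). T and B cell markers (0.02, 0.54), neutrophil and mast cell markers (0.04, 0.18), and skeletal muscle and blood markers (−0.02, 0.54) were not called either. The same held for heat shock genes (−0.02, 0.48; camera direction upward), immediate early genes (0.09, 0.41) and epididymis and testis markers (−0.02, 0.41). Camera did call inflammatory genes higher without day 14 array 1 (adjusted p = 0.023) or 4 (0.037). It called the respiratory chain lower without array 2 (0.018) or 4 (0.012). Without array 3 it called the tricarboxylic acid cycle (0.046) and neutrophil and mast cell markers (0.048) higher. Of 10 measured genes fixed in advance, Ucp1 and Adipoq are given above. Scd1, the main desaturase, stood at 0.08 ± 0.17 (SE, fit of all arrays), leptin, Lep, at 0.00 ± 0.10, Fasn at 0.19 ± 0.23 and Lpl at −0.23 ± 0.35. Fabp4 stood at 0.18 ± 0.39, Tnf at 0.23 ± 0.13, Cpt1a at 0.24 ± 0.13 and Pparg at −0.59 ± 0.32, and none of these 8 was past the threshold in either fit. Ucp2 had no probe naming it alone. The smallest p-values of the fit of all arrays, none passing, belonged to Olr1, Maoa (0.85 ± 0.09), Tnfrsf12a (0.79 ± 0.10), Ucp1 and Nabp1 (0.97 ± 0.12) on the higher side. On the lower side they belonged to Prodh (−0.56 ± 0.08), Gstm3 (−0.94 ± 0.14), Paip2b (−0.75 ± 0.12), Crip2 (−0.61 ± 0.10) and Sox13 (−0.62 ± 0.10).

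**Figure D2:**
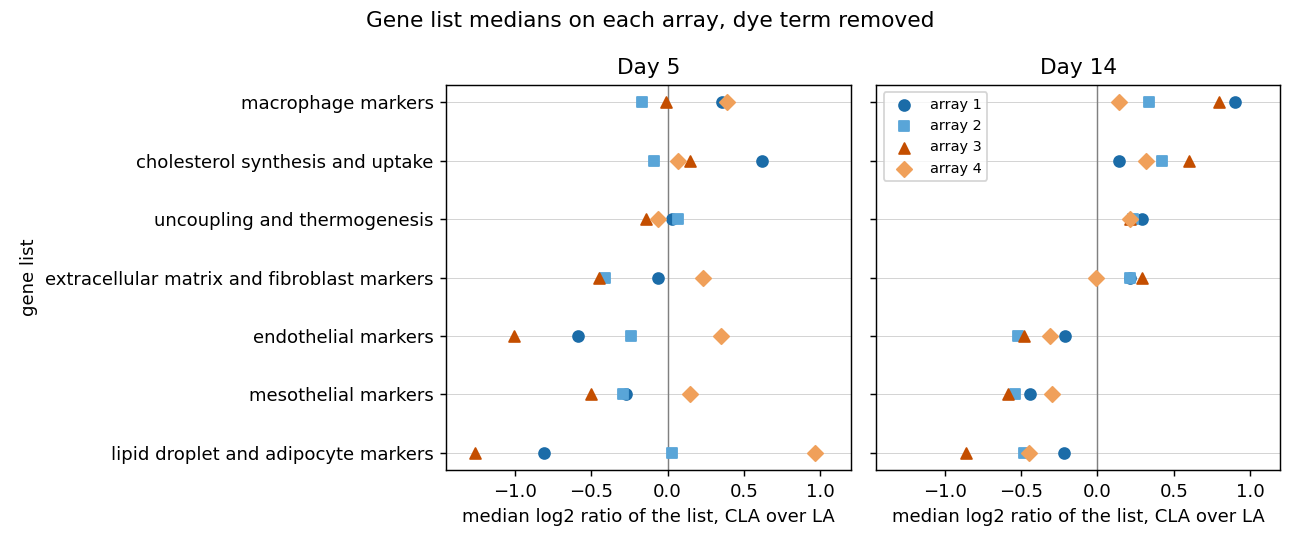
Median log2 ratio of CLA over LA (likely direction) of 7 gene lists on each array at day 5 and day 14, with the dye term removed; points are arrays. At day 14 the mesothelial median lies between −0.59 and −0.30, whereas at day 5 the adipocyte median runs from −1.26 on array 3 to 0.97 on array 4.

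At day 5, endothelial markers were lower, with 14 of 15 members below 0 and a median of −0.36 (camera adjusted p = 0.0011, and adjusted p = 0.91 with an estimated correlation). The vessel glycoprotein Emcn stood at −0.67 ± 0.16 (SE, fit of all 8 arrays), Plvap at −0.36 ± 0.14 and the nitric oxide synthase Nos3 at −0.35 ± 0.13. Respiratory chain genes had a median of −0.11 and 33 of 42 members below 0 (camera adjusted p = 0.018, and adjusted p = 0.91 with an estimated correlation), with Ndufa4 at −0.43 ± 0.11 and Atp5a1 at −0.30 ± 0.08. Extracellular matrix and fibroblast markers had a median of −0.16 and 28 of 38 below 0, with the same pair of adjusted p-values, 0.018 and adjusted p = 0.91 with an estimated correlation. The pericyte receptor Pdgfrb was at −0.73 ± 0.16, decorin, Dcn, at −0.75 ± 0.18 and the protease Mmp14 at −0.43 ± 0.10, the 3 members that fell adjusted over the list alone. Proliferation genes had a median of 0.13 (camera adjusted p = 0.03) and epididymis and testis markers 0.36 (camera adjusted p = 0.037), both called higher, and both had an adjusted p = 0.91 with an estimated correlation. Turning arrays 3 and 4 ended all 5 calls, with medians of −0.20 for endothelial markers (adjusted p = 0.47), 0.11 for the respiratory chain (0.78), 0.06 for the matrix (0.84), −0.05 for proliferation (0.78) and 0.29 for epididymis and testis markers (0.78).

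At day 5 limma called 0 probes and 0 genes in the fit of all arrays, with 2922 probes (906 higher and 2016 lower) and 2206 genes (692 and 1514) at an unadjusted p under 0.05, and smallest adjusted p-values of 0.295 and 0.284. The day 5 arrays alone also gave 0 probes and 0 genes by limma, with 1057 and 764 at an unadjusted p under 0.05. With each array centred and scaled, limma called 299 probes at day 5, all lower. Over all genes 0 members of the lists were therefore called. Adjusted over the list alone, besides the 3 matrix genes, hexokinase Hk2 (−0.57 ± 0.12) and the kinase Akt1 (−0.39 ± 0.09) fell among genes of insulin and glucose handling, with Hk2 again in glycolysis. The other 21 lists were not called (adjusted p 0.061 to 0.97), among them adipocyte markers (median −0.28, adjusted p = 0.16), macrophage markers (0.15, 0.073) and thermogenesis genes (−0.03, 0.87). Some alternatives did call macrophage markers higher at day 5, namely the day 5 arrays alone (adjusted p = 0.021), no dye term (0.019), the array number as block (0.012) and the fits without day 5 array 2 (0.0015) or 3 (0.046) or without day 14 array 1 (0.029) or 4 (0.041). Adipocyte markers were called lower without the dye term (0.0098), with the block (0.032) and without day 5 array 2 (0.043). Cholesterol synthesis and uptake (0.16, 0.061) was called higher with the day 5 arrays alone (0.032), without the dye term (0.015), with the block (0.032), without day 5 array 2 (0.0022), 3 (0.046) or 4 (0.03) and without day 14 array 1 (0.037) or 3 (0.047). Mesothelial markers were called lower without the dye term (0.015), with the block (0.031) and without day 5 array 1 or 4 (0.023 each). Fatty acid oxidation, the tricarboxylic acid cycle, insulin and glucose handling, the integrated stress response, interferon response, ribosomal proteins and immediate early genes each gained a call under 1 to 3 alternatives. Adiponectin, Adipoq, was at −0.93 ± 0.62 and Ucp1 at 0.80 ± 0.43. Scd1 (0.00 ± 0.17), Lep (−0.03 ± 0.10), Fasn (−0.23 ± 0.23), Lpl (0.01 ± 0.35), Fabp4 (0.45 ± 0.39), Tnf (0.15 ± 0.13), Cpt1a (−0.14 ± 0.13) and Pparg (−0.42 ± 0.32) did not pass either. The smallest p-values, none passing, were those of Ssx2ip (1.00 ± 0.17), Vwa5b1 (0.69 ± 0.11), Sox2 (0.43 ± 0.07), Zdhhc13 (0.50 ± 0.10) and Tcea2 (0.70 ± 0.14) on the higher side. On the lower side they were those of Ecrg4 (−0.78 ± 0.11), Lama5 (−0.67 ± 0.10), Pnrc2 (−0.46 ± 0.07), Adh5 (−0.56 ± 0.09) and H2ac8 (−0.71 ± 0.12).

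Single day 5 arrays decided these list calls, and 2 of them held high values of genes known from testis or epididymis. On array 3 the 7 measured testis genes had a median of 4.53 log2 units as deposited, with the protamine gene Prm1 at 6.78 and the transition protein gene Tnp1 at 6.51. On array 1 the 11 measured epididymis genes had a median of 2.53, with the lipocalin Lcn5 at 2.83 and Gpx5 at 2.53. The median of the epididymis genes on array 3 was −1.02. Adipocyte markers had medians of −0.81, 0.03, −1.26 and 0.97 on arrays 1 to 4, and the endothelial medians were −0.59, −0.24, −1.01 and 0.35. Without array 3 the endothelial median was −0.12 (adjusted p = 0.49), that of the matrix −0.07 (0.69), of proliferation 0.03 (0.87) and of epididymis and testis markers 0.14 (0.53). Without array 1 the medians were −0.07 for the respiratory chain (0.41), 0.06 for proliferation (0.34) and −0.08 for epididymis and testis markers (0.82), and without array 2 that of the matrix was −0.11 (0.33). From 4 to 13 lists were called as 1 array was left out, against 5 with all, with the 13 reached without array 4. With arrays 1 and 3 of day 5 left out together the median of the adipocyte list was 0.44 (adjusted p = 9.6e-08), whereas without array 4 it was −0.74 (adjusted p = 1.5e-07). With arrays 1 and 3 left out, 22 probes were called at day 14.

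**Figure D3:**
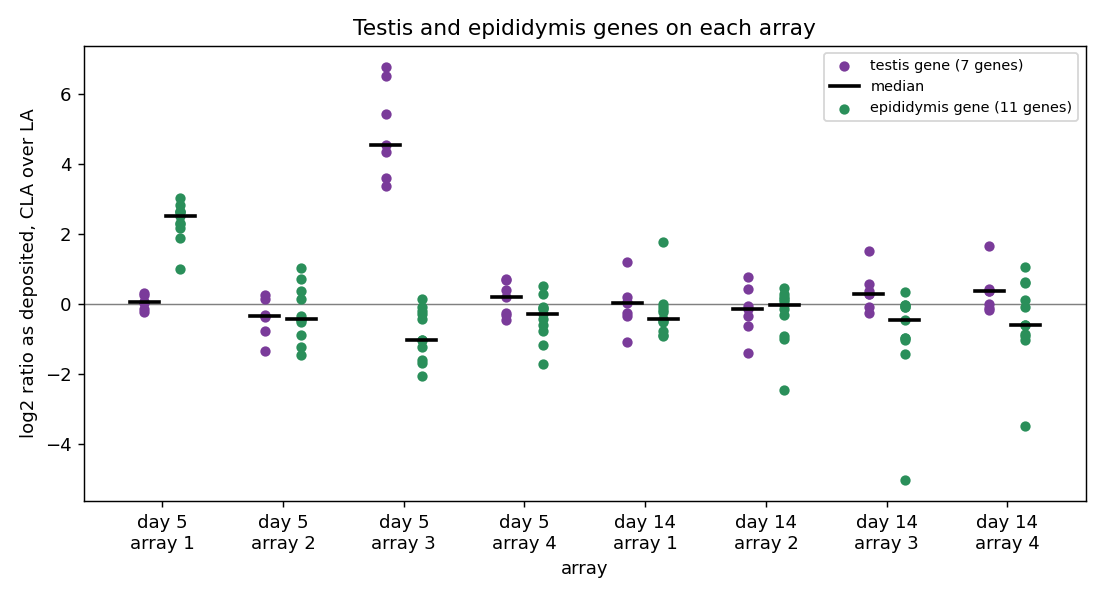
Log2 ratio as deposited, CLA over LA (likely direction), of 7 testis genes and 11 epididymis genes on each of the 8 arrays; points are genes and horizontal bars are medians. The testis median is 4.53 on day 5 array 3 and the epididymis median is 2.53 on day 5 array 1, whereas the medians of the remaining arrays and tissues lie between −1.02 and 0.38.

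The difference between the days asked which CLA effects were larger at day 14 than at day 5. Macrophage markers were higher at day 14 relative to day 5, with 32 of 33 members above 0 and a median difference of 0.46 (camera adjusted p = 8.3e-10, and adjusted p = 0.49 with an estimated correlation). Extracellular matrix and fibroblast markers had a median difference of 0.34 and 32 of 38 above 0 (camera adjusted p = 1.1e-08, and adjusted p = 0.49 with an estimated correlation). Thbs2, at 1.13 ± 0.24 (SE, fit of all 8 arrays), and Mmp14, at 0.70 ± 0.15, rose adjusted over the list alone, whereas Lum stood at 1.00 ± 0.27 and Lox, which cross-links collagen, at 0.67 ± 0.17. Genes of uncoupling and thermogenesis had a median difference of 0.23 (camera adjusted p = 1.5e-05, and adjusted p = 0.11 with an estimated correlation). For this contrast fry also called this list (adjusted p = 0.028), again with Ucp1 among its members. Ucp1 differed by 2.71 ± 0.61, Cox8b by 1.11 ± 0.23, Cox7a1 by 0.68 ± 0.21 and Elovl3 by 0.59 ± 0.20, the 4 members at or under the threshold adjusted over the list alone. Fatty acid oxidation genes had a median difference of 0.19 (camera adjusted p = 4.3e-05, and adjusted p = 0.49 with an estimated correlation), with Etfdh, an electron carrier of that pathway, at 0.62 ± 0.14 as the 1 member that rose adjusted over the list alone. With day 5 arrays 1 and 3 left out together the median of this list was 0.13 (adjusted p = 0.16). Turning arrays 3 and 4 gave median differences of 0.12 for macrophages (adjusted p = 0.3), 0.16 for the matrix (0.057), −0.04 for thermogenesis (0.57) and 0.06 for fatty acid oxidation (0.69).

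Limma called 0 probes and 0 genes for the difference, with 931 probes (606 higher and 325 lower) and 700 genes (463 and 237) at an unadjusted p under 0.05, and smallest adjusted p-values of 0.914 and 0.892. Camera called 13 of the 26 lists, 9 higher and 4 lower, and none held with an estimated correlation (adjusted p 0.11 to 0.81). Besides the 4 lists above, fatty acid and triglyceride synthesis was called higher (median difference 0.20, adjusted p = 0.0035, and adjusted p = 0.61 with an estimated correlation). So were cholesterol synthesis and uptake (0.29, 0.012, and adjusted p = 0.63 with an estimated correlation) and immediate early genes (0.18, 0.019, and adjusted p = 0.49 with an estimated correlation). Inflammatory cytokines and acute phase genes (0.08, 0.03, and adjusted p = 0.61 with an estimated correlation) and neutrophil and mast cell markers (0.10, 0.047, and adjusted p = 0.49 with an estimated correlation) were the remaining 2 of the 9. Called lower were epididymis and testis markers (−0.67, 0.0035, and adjusted p = 0.54 with an estimated correlation) and adipocyte markers (−0.26, 0.02, and adjusted p = 0.81 with an estimated correlation). The same held for ribosomal proteins (−0.07, 0.029, and adjusted p = 0.81 with an estimated correlation) and mesothelial markers (−0.21, 0.047, and adjusted p = 0.61 with an estimated correlation). Turning arrays 3 and 4 turned the adipocyte call, with a median difference of 0.38 called higher (adjusted p = 0.039), and ended the other 8. The medians were then −0.05 for fatty acid synthesis (0.53), −0.22 for cholesterol (0.057), −0.07 for immediate early genes (0.26), −0.07 for inflammatory genes (0.26) and −0.02 for neutrophil and mast cell markers (0.7). They were −0.11 for epididymis and testis markers (0.53), −0.05 for ribosomal proteins (0.26) and 0.02 for mesothelial markers (0.88). Each of these 9 calls was also lost when 1 array was left out. Without day 5 array 3 the median was 0.09 for fatty acid synthesis (adjusted p = 0.61), −0.10 for epididymis and testis markers (0.28) and 0.08 for immediate early genes (0.27). Without day 5 array 4 it was 0.22 for adipocyte markers (0.15), 0.16 for cholesterol synthesis (0.15) and −0.04 for mesothelial markers (0.55). Without day 5 array 1 it was 0.01 for ribosomal proteins (0.89), 0.02 for inflammatory genes (0.17) and 0.06 for neutrophil and mast cell markers (0.2).

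By gene, the smallest p-values of the difference, none passing, belonged to Maoa (0.81 ± 0.13), which encodes a monoamine oxidase, Alg14 (0.98 ± 0.16), Dennd2a (0.64 ± 0.11), H2ac8 (0.96 ± 0.17) and Olr1 (1.39 ± 0.25). On the lower side they were those of Ssx2ip (−1.35 ± 0.24), Paip2b (−0.80 ± 0.16), Sort1 (−0.75 ± 0.17), Slc35f4 (−0.57 ± 0.14) and Cldn34c4 (−0.92 ± 0.24). Across the 16504 genes, which are not independent replicates, the effects of the 2 days correlated with r 0.36 (Spearman's rho 0.36), and 62.4% of genes had the same sign. Of the 260 genes called from the day 14 arrays alone, 237 had the same sign at day 5, 78 of them higher and 159 lower, and 62 had an unadjusted p under 0.05 there. These values, and the share of all genes with the same sign, hold only for the direction taken here. With the arrays of the opposite dye orientation turned, the day 14 arrays alone called 5248 genes in place of 260. The orientation difference, which turning would have made the effect, correlated between days with r 0.75 across genes. Shares of genes with the same sign are not given for that setting.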

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

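The tests of the 3 patterns weighed here were chosen only after results were seen, except that of exchanged pools; the counts over other sign patterns and splits were planned, apart from that for the day 14 arrays alone.

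Among 282 groups of 4 arrays tested, 11 held an array far from the other 3 by Dixon's test. Chance picks about 1 in 20 independent groups, or 14.1. These groups are not independent, and some of their genes were chosen for their values. The number 14.1 therefore cannot decide whether these 11 arose by chance. At day 5, Gstm3 stood at −0.04 on array 3 (others −0.50 to −0.44), Insl3, a Leydig cell hormone gene, at 3.99 on array 3 (0.08 to 0.61), Spink12, an epididymis gene, at 2.06 on array 1 (−0.27 to −0.18) and Pfkl at 0.76 on array 1 (−0.05 to −0.01). At day 14, Olr1 stood at 1.39 on array 4 (1.93 to 1.99), Pla2g2e at 0.67 on array 1 (1.68 to 1.74) and Tnfrsf12a at 1.05 on array 3 (0.67 to 0.73). Of list medians at day 14, fatty acid and triglyceride synthesis stood at 0.04 on array 1 (0.21 to 0.25), epididymis and testis markers at −0.08 on array 1 (the others at −0.24), the tricarboxylic acid cycle at −0.22 on array 3 (0.08 to 0.10) and immediate early genes at 0.12 on array 3 (−0.01 to 0.00). All are log2 values with the dye term removed.

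By camera at the preset correlation, 13 lists differed between the days in their CLA effect. The median differences were 0.46 for macrophage markers, 0.34 for extracellular matrix and fibroblast markers, 0.29 for cholesterol synthesis and uptake, 0.23 for uncoupling and thermogenesis, 0.20 for fatty acid and triglyceride synthesis, 0.19 for fatty acid oxidation, 0.18 for immediate early genes, 0.10 for neutrophil and mast cell markers and 0.08 for inflammatory cytokines and acute phase. They were −0.67 for epididymis and testis markers, −0.26 for lipid droplet and adipocyte markers, −0.21 for mesothelial markers and −0.07 for ribosomal proteins. With an estimated correlation 0 lists differed. Among 34 splits of the 8 arrays into 4 and 4, a set that includes the real one, 4 gave as many lists as the real 13, the highest other being 13. As to probes, 14 gave as many at an unadjusted p under 0.05 as the real 931, the highest other being 3280. Chance could not be excluded for either. A 35th split follows the dyes and could not be fitted.

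On day 5 array 3, 7 of the 7 measured testis genes, from sperm-forming and Leydig cells, stood over 1 log2 unit, and on array 1, 10 of the 11 epididymis genes did. One hypothesis is that testis RNA entered 1 pool of array 3 and epididymis RNA 1 pool of array 1, as the epididymal fat pad lies against both organs. It was drawn from these same values and stays open. It does not cover the epididymis genes on array 3, whose median was −1.02, with single genes from −2.06 (Lcn5) to 0.16 (Defb2). Dye bias was excluded by the arrays with the same dyes, with a testis median of 0.22 on array 4 and an epididymis median of −0.43 on array 2. A CLA effect on these genes shared by the day 5 pools was excluded, since 1 of the 4 arrays had a testis median over 1 log2 unit. An effect of CLA in single mice of a pool was not tested.

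Adipocyte markers split the day 5 arrays, and dye bias alone was excluded because the median of array 3 minus that of array 4, with the same dyes, was −2.22, against a size of at most 0.40 between day 14 arrays with the same dyes. On array 3 a different share of adipocytes alone was excluded by the endothelial median of −1.01, though not such a share together with dilution. Dilution of adipose RNA by testis or epididymis RNA stays open on array 4, with an epididymis median of −0.28 but Defb2 at −1.72, and on arrays 1 and 3, since the macrophage median lay 1.25 above the adipocyte median on array 3, which a rise of macrophages in the same pools could also give. An exchange of the pools of array 4 stays open too, with r −0.08 across genes between array 4 and the day 14 effect, a size that decides nothing, against 0.46, 0.27 and 0.16 for arrays 1 to 3. Whether CLA changed adipocyte transcripts at day 5 is likewise undecided.

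Higher macrophage and lower adipocyte markers at day 14 might reflect an effect of CLA on the tissue, a hypothesis these arrays leave open. A lower share of adipocytes alone would raise mesothelial and endothelial markers. The mesothelial median was −0.41, with mesothelial and endothelial medians below 0 on all 4 arrays. This argues against such a share only if the direction taken here is right, as the mesothelial median was 0.05 with arrays 3 and 4 turned. Neither list call held with an estimated correlation, and a change in the shares of other cells was not weighed. Dye bias was excluded by macrophage medians of 0.72 on arrays 1 and 2 and 0.37 on arrays 3 and 4 as deposited, which holds only if the direction taken here is right. RNA of testis or epididymis in a pool would, by dilution alone, move both kinds of markers the same way. With the dye term removed, macrophage medians were 0.90, 0.34, 0.80 and 0.14 on the 4 arrays, and adipocyte medians −0.22, −0.48, −0.86 and −0.45. These opposite signs argue against such RNA as the only cause. Whether it had a part stays open. The farthest median of the testis or epididymis genes on a day 14 array was −0.58. Single epididymis genes lay farther from 0, with Lcn5 at −5.03 on array 3 and Gpx5 at −3.47 on array 4.

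For day 5, 2 of 8 sign patterns of the arrays gave as many probes at an unadjusted p under 0.05 as the real 2922, the highest other being 4683 with array 4 turned. Of the same patterns, 7 of 8 gave as many lists as the real 5, the highest other being 15. For day 14, 1 of 8, the real pattern, reached 2054 probes, the highest other being 673, and 1 of 8 reached 15 lists, the highest other being 9. With the day 14 arrays alone, 1 of 7 patterns, the real one, reached 260 genes, the highest other being 0. The pattern not among these 7 follows the dyes, and it called 5248 genes when arrays 3 and 4 were turned. With 8 or 7 patterns a share under 0.05 cannot be reached.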

How the results depend on the processing

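Of the tests here, that of genes on the day 14 arrays alone, with its repeats, and that of gene lists on the arrays of 1 day were chosen only after results were seen. So were 4 kinds of alternatives, namely arrays 3 and 4 turned, arrays weighted by quality, day 5 arrays 1 and 3 left out together, and a dye term per day or probes with 1 symbol only. Where a value moved, the cause was not tested.

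With arrays 3 and 4 turned, 3752 probes (1967 higher and 1785 lower) were called at day 5 and 3764 (1829 and 1935) at day 14, and 0, 0 and 3 lists at day 5, at day 14 and for the difference. Probes called, 0 in each comparison, moved to 299 lower at day 5 with centring and scaling. At day 14 they moved to 96 with the arrays of the day, 393 with weighted arrays (165 higher and 228 lower) and 22 with day 5 arrays 1 and 3 left out (9 and 13). The difference then gave 1 (Ucp1, 3.87, adjusted p = 0.007). As each array was left out the count ran from 0 to 0 at day 5, 0 to 1 at day 14 (Olr1, 1.82, adjusted p = 0.039) and 0 to 0 for the difference. Lists called at day 5, 5 at first, were 0 with an estimated correlation, 0 with fry, 11 without the dye term, 9 with the array number as block and 4 to 13 as each array was left out. For day 14 (15) they were 0, then 1 with fry and 14 to 16, and for the difference (13) 0, 1 and 10 to 13. Genes called from the day 14 arrays alone (260) were 5248 with arrays 3 and 4 turned (2780 higher and 2468 lower). Of the 20 named from that fit, 14 then had the other sign: Ucp1 −0.08, Timp1 −0.28, Pla2g2e −0.02, Hsd17b12 −0.30, Fabp3 −0.27, Nnat 0.67, Car3 0.61, Tmem45b 0.40, Adipoq 0.72, Mest 0.53, Apcdd1 0.35, Slc1a3 0.23, Hsd11b1 0.42 and Sucnr1 0.69. Of these, Hsd17b12, Tmem45b, Mest, Hsd11b1 and Sucnr1 were called in that other direction. Olr1 (0.62), Pdk4 (0.81) and Insig1 (0.44) kept their call, whereas Dhcr7 (0), Chac1 (0.28) and Sfrp5 (−0.30) lost it. The count was 1 without the dye term (Ucp1, adjusted p = 0.0043), 28 against a 1.2-fold change (6 higher and 22 lower), 58 with arrays 1 and 4 and arrays 2 and 3 averaged (27 and 31), and 1 to 156 as each array was left out. Without array 1 or 2 the 1 was Ucp1 (3.63 and 3.40, adjusted p = 0.0094 and 0.013). Centring (249), scaling (315), robust eBayes (246), 1 probe per gene (199) and the other averaging (324) kept that count within 1.5 times.

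The direction of the list test reversed in 37 cases where a call was made, and in 34 of them the median took the other sign. In the other 3 the median of the main fit was 0 after rounding, so signs could not be compared. These 3 were of fatty acid synthesis at day 5 and the integrated stress response for the difference. With arrays 3 and 4 turned the medians of the 37 cases were, at day 5, 0.11 for the respiratory chain, 0.06 for the matrix and −0.05 for proliferation. At day 14 they were 0.34 for adipocyte markers, −0.05 for fatty acid synthesis, −0.10 for cholesterol, −0.08 for thermogenesis, −0.15 for glycolysis, 0.05 for mesothelial markers, −0.17 for the integrated stress response, 0.07 for interferon and 0.06 for ribosomal proteins. For the difference they were 0.38 for adipocyte markers, −0.05 for fatty acid synthesis, −0.22 for cholesterol, −0.04 for thermogenesis, −0.07 for inflammatory genes, −0.02 for neutrophil and mast cells, −0.24 for the integrated stress response and −0.07 for immediate early genes. With day 5 arrays 1 and 3 left out they were, at day 5, 0.44 for adipocyte markers, 0.16 for fatty acid synthesis, 0.11 for the tricarboxylic acid cycle, 0.06 for endothelial markers, −0.27 for epididymis and testis and −0.08 for proliferation. For the difference they were −0.15 for the tricarboxylic acid cycle, −0.12 for inflammatory genes, −0.40 for endothelial markers, 0.14 for epididymis and testis and 0.06 for ribosomal proteins. Weighted arrays gave −0.02 for proliferation at day 5. As each array was left out, medians ran at day 5 from −0.14 to 0.09 (without array 3) for fatty acid synthesis and from −0.08 (without array 1) to 0.81 for epididymis and testis. For the difference they ran from −0.64 to 0.22 (without day 5 array 4) for adipocyte markers, −0.31 (without array 3) to 0.24 for endothelial markers and −0.16 to 0.01 (without array 1) for ribosomal proteins.

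Of the other list medians under an alternative, 1140 kept their side of the threshold, 135 lost their call and 66 gained one. The median itself took the other sign in 99, 3 and 1 of these. The 3 were inflammatory genes for the difference (−0.03 without day 5 array 3 and −0.04 with weighted arrays, against 0.08) and mesothelial markers for the difference (0.02 with arrays 3 and 4 turned, against −0.21). The 1 was the tricarboxylic acid cycle at day 14 (0.03 without array 3, against −0.02). Of counts, 105 stayed within 1.5 times and 29 did not. Named genes, none called in the fit of all arrays, stayed uncalled in 3893 cases, where their sign was not compared. Only 1 gained a call (Olr1 at day 14 without day 5 array 2, adjusted p = 0.026). The 20 genes of the day 14 fit kept their call in 153, lost it in 93 and had the other sign in 14. The array number as block changed no probe count. Deviations of arrays with the same number correlated with r −0.65, −0.47, −0.34 and 0.14 between days. The dye term shared by the days itself pushes such correlations below 0, so they cannot decide whether the numbers pair. Not run were the planned settings for missing values (none missing), dim spots (no intensities, no exact 0) and single days for the difference (not possible). Without intensities, what signal over background limits could not be measured.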

Other observations

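The tests below on gene lists in the fit of all arrays were set in advance, whereas the tests of genes on the day 14 arrays alone, and the choice of Pfkfb3 from them, came only after results were seen.

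Beyond lipid and cell type markers, 6 lists were called at day 14. Hmox1, the haem oxygenase induced by oxidative stress, stood at 1.33 ± 0.30 (SE, fit of all arrays). Genes of oxidative stress and metallothioneins had a median of 0.11, with 19 of 27 above 0 (camera adjusted p = 0.011, and adjusted p = 0.33 with an estimated correlation). Hmox1 and the thioredoxin reductase Txnrd1 (0.52 ± 0.13) rose and Gstm1 (−0.64 ± 0.13) fell adjusted over the list alone. Glycolysis had a median of 0.14, with 10 of 14 above 0 (camera adjusted p = 0.014, and adjusted p = 0.37 with an estimated correlation). Of its members, Pkm (0.51 ± 0.10), Pgam1 (0.41 ± 0.09) and Pfkl (0.79 ± 0.21) rose adjusted over the list alone. Pfkfb3, which makes an activator of phosphofructokinase, fell by 1.25 ± 0.12 with the day 14 arrays alone, as the 1 member called over all genes. The integrated stress and unfolded protein response had a median of 0.17, with 17 of 29 above 0 (camera adjusted p = 0.029, and adjusted p = 0.56 with an estimated correlation). There Chac1 and the hormone gene Fgf21 (0.43 ± 0.09) rose adjusted over the list alone, whereas Phgdh, of serine synthesis, stood at −0.82 ± 0.23.

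Proliferation genes had a median of 0.14, with 28 of 33 above 0 (camera adjusted p = 0.0014, and adjusted p = 0.56 with an estimated correlation). Mki67 stood at 0.25 ± 0.09 (SE) and Tk1 at 0.36 ± 0.15. Interferon response genes were lower, with a median of −0.13 and 22 of 26 below 0 (camera adjusted p = 0.014, and adjusted p = 0.58 with an estimated correlation). B2m, the light chain of class I molecules, stood at −0.70 ± 0.24. Ribosomal proteins had a median of −0.10, with 37 of 44 below 0 (camera adjusted p = 0.0038, and adjusted p = 0.58 with an estimated correlation). Among neutrophil and mast cell markers, which were not called, the receptor gene Csf3r (0.47 ± 0.11) rose adjusted over the list alone, and the mast cell proteases Cpa3 and Cma1 stood at 1.29 ± 0.41 and 0.35 ± 0.10. In the fit of all arrays limma called 0 members of these lists over all genes, as it called none of the array's genes, 1612 of which had an unadjusted p under 0.05. Turning arrays 3 and 4 ended all 6 calls, with medians of 0.10 for oxidative stress (adjusted p = 0.5), −0.15 for glycolysis (0.5), −0.17 for the integrated stress response (0.5), 0.04 for proliferation (0.98), 0.07 for interferon (0.98) and 0.06 for ribosomal proteins (0.98). Single arrays decided 4 of the calls. The median was −0.05 for ribosomal proteins without day 14 array 1 (adjusted p = 0.38) and 0.12 for oxidative stress without array 4 (0.06). It was −0.11 and −0.12 for interferon without array 1 or 2 (0.14 and 0.13). It was 0.09, 0.07 and 0.10 for the integrated stress response without array 2, 3 or 4 (0.098, 0.11 and 0.16), and 0.17 without day 5 array 3 (0.069).

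The standard deviation between genes of the dye term was 0.344 log2 units, against 0.265 for the day 5 and 0.232 for the day 14 effect. Array weights ran from 0.20 on day 5 array 3 to 2.84 on day 5 array 2. The difference between arrays 1 and 2 correlated across genes with that between arrays 3 and 4 with r 0.23 at day 5 and −0.03 at day 14.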
